A study of Rattus norvegicus with 27 samples.

How the data were processed

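Tumour DNA was compared with normal kidney DNA on 27 Agilent 244A arrays for comparative genomic hybridisation. Each array carried 1 malignant mesothelioma in red (Cy5) and normal kidney in green (Cy3), per the labels, and both came from F1 hybrids of Fischer 344 and Brown Norway rats. Dyes were not swapped on any array, so a dye effect of a probe cannot be separated from its ratio in the mean over tumours. DNA was extracted with a column kit, per the labels' protocols.

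The fibre label (Chry, Cro, Amo) and the tumour type label (EM, BM, SM) were taken from the sample titles. Chry, Cro and Amo are read here as chrysotile, crocidolite and amosite, and EM, BM and SM as epithelioid, biphasic and sarcomatoid, from what is known of the study. There were 9 tumours per fibre, and 9 EM, 8 BM and 10 SM tumours. The labels do not say whether tumours came from separate animals, so p-values measure the spread between these samples.

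The deposited scanner files hold spot intensities, and the processed red and green intensities had been background-subtracted, spatially detrended and dye-normalised by Agilent Feature Extraction, per the file headers. The submitters' processing notes name version 9.5. The headers name version 9.1.3.1 for 11 arrays, called the first set-up here, and version 9.5.1.1 for 16 arrays, called the second set-up. Arrays were scanned on 8 days, with 2 to 4 arrays each. The deposited value table holds the log10 ratio of red over green per the file headers, identical to the scanner files' own log ratio with a largest difference of 0. Its column medians ran from -0.0325 (Amo SM 4) to 0.0134 (Chry SM 1). Of the deposited 0 or 1 marks, those for outlying spots were used as a filter, those for well-above-background spots only in an alternative, and those for saturated spots were only counted. Probe positions are those of the array files, and the genome build is not given in the sources used here.

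Of 237974 spots that were not controls, 235974 were distinct probes, and 231349 had a chromosome position, 220042 of them on autosomes. Outlying spots were left out, at most 439 per array, and saturated spots, at most 10 per array, were kept. The log2 ratio of processed red over processed green was centred on each array's median over autosomal probes, with no loess or quantile step, and probes spotted more than once were averaged. Probe noise, from differences between neighbouring probes, ran from an SD of 0.19 in Chry EM 3 to 0.71 in Amo EM 1. Over the arrays, 73.3% to 100.0% of reference spots and 46.4% to 100.0% of tumour spots were well above background, lowest in Amo SM 1 and Amo EM 1. The number of arrays limits the precision of every group value.

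Values were summarised as medians of 1-Mb bins with at least 10 probes, which gave 2555 autosomal bins, and as gene means over the probes that the files name by a gene. Of the gene names in the files, 5459 matched a current symbol of the rat gene table (assembly GRCr8), 1864 a synonym and 416 a gene identifier, while 1919 were kept as the files give them. A name was left out if its probes lay on more than 1 chromosome or spanned over 3 Mb (55 names), and 9270 autosomal genes were tested, 2154 of them by 1 probe. Segments came from penalised least squares (PELT) per chromosome and array, with a penalty of 10 times the probe noise variance times the natural log of the number of probes and at least 5 probes. A segment at or beyond 0.25 in size was called lost or gained, one at or below -1 a deep loss and one at or above 1 a high gain.

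Bins and genes were tested with limma (version 3.58.1, R 4.3.3; lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. The mean over tumours was set against 0, which leaves out the spread of the reference itself. Each pair of fibres was tested with tumour type as a term, each pair of types with fibre as a term, and a moderated F test covered their interaction. Shares of the genome and gene list means were compared by exact permutation tests and Cdkn2a deletion by Fisher's exact test, all 2-sided. Recurrence was judged against 1000 circular shifts of each tumour's calls, and a bin was recurrent if more tumours had the call than the 95th percentile of the shifted maximum. The segment steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

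The tests, the 8 gene lists and the rule for named genes were fixed before the data were examined, except that a count equal to the shifted percentile could be read as recurrent or not; it was first read as recurrent and then not, after the data had been seen. Cdkn2a, Cdkn2b, Mtap, Nf2, Bap1, Erbb2, Met, Myc and Tfrc were always named where measured. To these the rule added up to 4 members of each list with the greatest change past the threshold, and the 10 lowest and 10 highest genes past it. For each pair of groups it took the 10 genes of smallest p past the threshold, or, where none passed, the 3 of smallest p given as values that did not pass. It also took genes in deep losses or high gains of at least 3 tumours. Genes of each such set were taken at most once per 10-Mb window. The sex chromosomes stayed out of the main tests, since rats of both sexes were used and the sex of each tumour and of the reference is not labelled; the X chromosome is given among other observations. Of 108 listed genes, 69 had a probe under their own name on an autosome; values of some genes are not reported here. For 37 of the other 39, the mean over the probes between the nearest named neighbours was added after seeing the files, with neighbours taken from the order of genes in the rat gene table.

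The methods were tested on simulated data. With 200 of 2555 bins shifted by 0.2, limma recovered 93.8% of them in the mean over all tumours and 12.5% in Chry against Cro, and with a shift of 0.4 it recovered 86.3% in Chry against Cro. At the real noise of the arrays, segmentation recovered 85.6% of losses of -1 over 50 probes, 43.7% over 20 probes and 14.4% over 10 probes. Losses of -0.5 over 50 probes were recovered in 19.6%, so small or shallow changes were mostly not callable. Of the simulated bins called by limma, 4.02% to 6.02% were false. Simulated bins were independent draws of normal noise, while real neighbouring bins share segments, so the shares recovered and false need not hold for the real data. Shifted calls with no shared region gave a recurrent bin in 0 of 40 sets, and a region of 20 bins lost in 14 tumours was found in 40 of 40. The planted 14 tumours exceed the loss threshold of 10 in the real calls, so the latter result was nearly fixed in advance. It says nothing about how often regions with counts near the threshold are found. With no difference, 4.84% of 5000 exact permutation tests of 9 against 9 had p under 0.05; the number of simulated sets was raised to this after a smaller run gave a higher share.

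Alternatives covered normexp background correction (offset 50) of the mean and background signals, centring on the mode of the bins, probes well above background on all arrays (73048 probes), the deposited value table and 5-Mb bins. They also covered replicate number and scan day as blocks, array weights, no second factor, other segmentation and call thresholds, permutation within the other factor, and each array left out in turn. Added after seeing the data were the set-up as a block, each set-up alone, 2 similar pairs of tumours, the 2 dim arrays, another weighting of the replicate block and another reading of the recurrence threshold.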

Results

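Copy number was measured in 27 malignant mesotheliomas of asbestos-treated F1 rats, with normal kidney DNA of the same hybrid as the reference on each array. The design crossed 3 fibre labels (Chry, Cro and Amo, 9 tumours each) with 3 tumour type labels (EM, 9 tumours; BM, 8; SM, 10). It asks which regions these tumours lost or gained, and whether fibres or tumour types differ in them. Values are log2 ratios of tumour over reference, centred on each array's autosomal median, so a change is relative to the middle of that tumour's genome. The median mean signal of the tumour channel ran from 52.1 in Amo SM 1 to 285 in Chry SM 1. Amo EM 1 and Amo SM 1 were dim, with 46.4% and 61.2% of tumour spots well above background.

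Relative to normal kidney, the tumours were on average lower over most of chromosomes 5, 8 and 20 and higher over most of chromosomes 4, 7 and 12. On chromosome 5, 146 of 174 bins were below the reference, with a mean of -0.21 over the chromosome and -0.94 in its lowest bin. On chromosome 8, 115 of 129 bins were below, with a mean of -0.17, and on chromosome 20, 44 of 56 bins, with a mean of -0.12. All 47 bins of chromosome 12 were above, with a mean of 0.18, as were 120 of 188 bins of chromosome 4, 84 of 143 of chromosome 7, 71 of 112 of chromosome 9 and 64 of 111 of chromosome 10. Chromosome 11 had no bin past the threshold in limma. In all, 942 of 2555 autosomal bins passed (limma, n = 27), 446 above and 496 below the reference, of which 241 were at 0.1 or higher and 408 at -0.1 or lower. Centring on the mode instead, which moved arrays by -0.20 (Cro SM 2) to 0.12 (Amo BM 1) and 6 of them by over 0.1, split the calls into 156 above and 702 below, and normexp into 340 above and 203 below.

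Loss of chromosome 5 was also the most recurrent call. Segments lost on chromosome 5 between 28 and 174 Mb reached 22 of 27 tumours at 108 to 109 Mb, where chance placement of each tumour's calls gave at most 10 tumours in 95% of shifts. Losses of chromosome 8 at 13 to 19 Mb reached 12 tumours, and those at 26 to 27 and 28 to 36 Mb 11 tumours. Recurrent gains lay on chromosome 7 at 55 to 59 Mb and 64 to 68 Mb and on chromosome 10 at 93 to 100 Mb, each in 8 tumours against a threshold of 7. In all, 161 bins were recurrently lost and 15 recurrently gained; normexp left 8 bins in all, and the first set-up alone 7. No gain was recurrent within either set-up (7 lost and 0 gained bins in the first, 171 and 0 in the second). With 1 tumour of each pair of similar profile left out 8 bins were recurrently gained, and with probes well above background on all arrays 87. Recurrently gained bins numbered 7 without the 2 dim arrays, 34 with centring on the mode and 47 at a call threshold of 0.15. Bins of chromosome 12 were gained in up to 6 tumours, which did not pass.

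**Figure D1:**
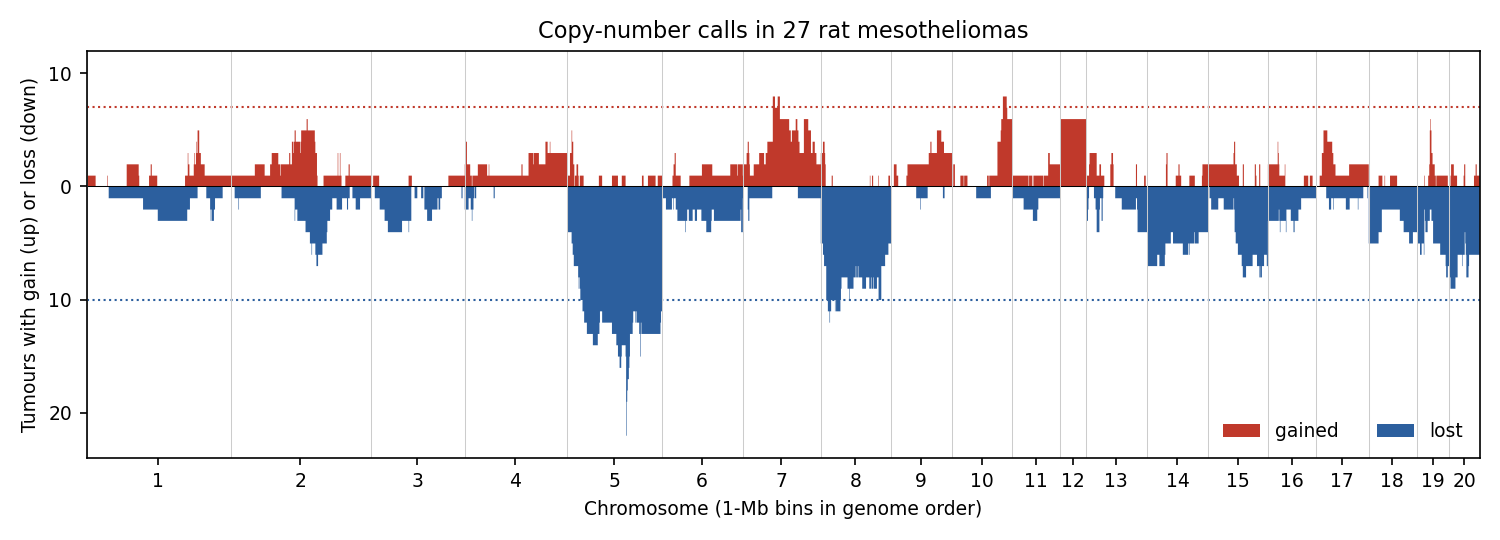
Number of tumours (of 27) with a gained segment (red, upward) or lost segment (blue, downward) in each 1-Mb bin of autosomes 1 to 20; dotted lines mark the thresholds of 7 tumours for gain and 10 for loss. Loss peaks in 22 tumours on chromosome 5, and gain in 8 tumours on chromosomes 7 and 10.

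The deepest shared loss lay over Cdkn2a and Cdkn2b, which encode the cell cycle inhibitors p16, p19ARF and p15, in the locus homologous to human 9p21. The mean log2 ratio was -1.02 for Cdkn2a (SD 1.00, n = 27; chromosome 5, 108911606 to 108914035, 2 probes; limma adjusted p = 0.000238) and -1.37 for Cdkn2b (SD 0.85, 1 probe; 1.66e-06). Mtap, which encodes a methionine salvage enzyme, had -1.03 (SD 0.73; 1.33e-05), and Elavl2, further along the chromosome, -0.59 (SD 0.52; 0.000100). All 4 measured genes of this list were lower, both over all genes and adjusted over the list alone. Cdkn2b was below 0 in 26 of 27 tumours and Cdkn2a in 24. Within the first set-up (n = 11) Cdkn2a was at -0.47 and did not pass, and within the second (n = 16) at -1.4; with normexp it was at -0.21, Cdkn2b at -0.62, Mtap at -0.34 and Elavl2 at -0.19, and all 4 passed. Elavl2 did not pass within the first set-up (-0.51).

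Segments over the Cdkn2a probes were deep losses in 18 of 27 tumours, down to -3.28 in Cro SM 2, and were called lost in 22. Chry EM 2 and Amo SM 4 lay just past the limit of -1. The share of tumour cells in each sample was not measured, so a deep loss was not shown to be loss of every copy. The part common to the 18 deep segments spanned 118 kb of chromosome 5, from 108879683 to 108997627, and held Cdkn2a and Cdkn2b as its named genes. The segment mean over the Mtap probes was deep in 14 tumours and that over the Elavl2 probes in 6. The count of 18 depends on where the line is drawn: it was 21 at -0.75 and 5 at -1.5, and 3 with normexp.

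Deep deletion of Cdkn2a was counted in fewer Cro than Chry or Amo tumours, but no pair of fibres or tumour types differed past the threshold. It was found in 7 of 9 Chry, 4 of 9 Cro and 7 of 9 Amo tumours, and in 6 of 9 EM, 6 of 8 BM and 6 of 10 SM tumours. The Amo tumours without it were those on the dim arrays, Amo EM 1 (0.15) and Amo SM 1 (-0.22). Probe noise was high there (SD 0.71 and 0.56), so a loss could be missed. Fisher's exact test gave p = 0.335 for Chry against Cro and for Cro against Amo, 0.638 for SM against BM and 1 for the other pairs, with adjusted p = 1 for all 6. Cro EM 3 and Cro BM 3 lay just above the limit at -0.94 and -0.96.

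**Figure D2:**
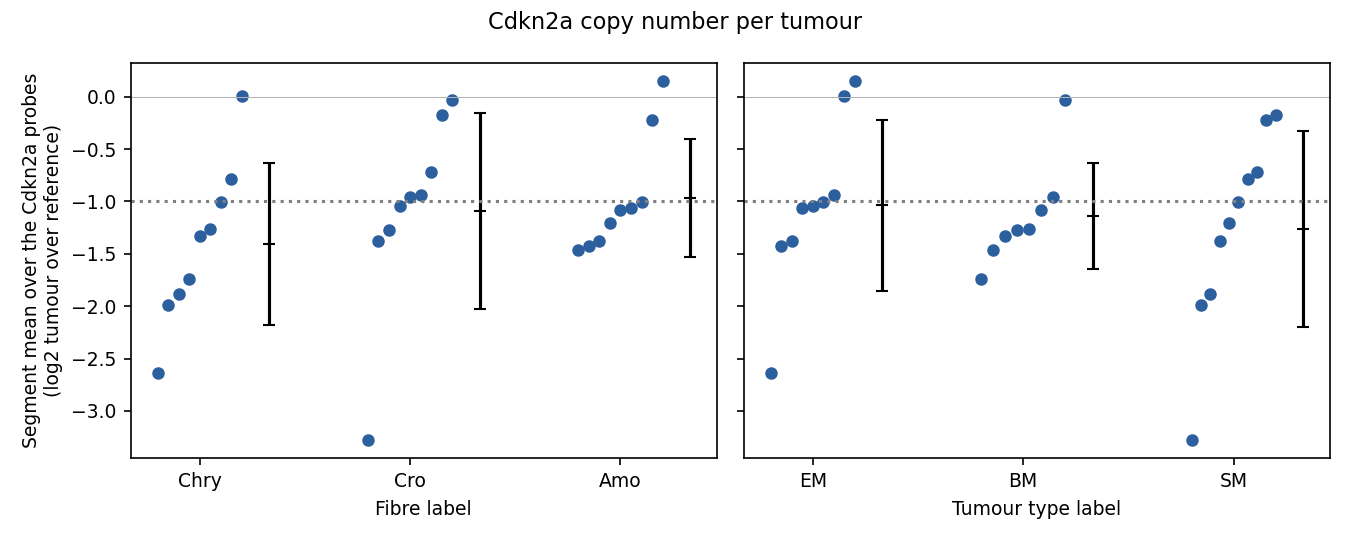
Mean log2 ratio of the segment over the Cdkn2a probes in each of 27 tumours (points), by fibre label and by tumour type label, with the group mean and SD (black bars) and the deep loss limit of -1 (dotted). Deep loss was seen in 7 Chry, 4 Cro and 7 Amo tumours, and the lowest value was -3.28 in Cro SM 2.

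A second window of chromosome 5, from 134044135 to 134592966, was deeply lost in 9 tumours: Chry EM 3, Chry BM 1, Chry BM 3, Chry SM 1, Chry SM 2, Chry SM 3, Cro EM 1, Cro EM 2 and Amo EM 3. The part shared by all 9 was 549 kb and held no named gene, and segment means there ran from -1.06 to -2.52. Of 16 tumours with flanks at -0.2 or lower, 8 had the window above the flanks by any amount, 4 of them by at least 0.15 and over 3 standard errors. This window was singled out after its values were seen.

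High gains gathered on chromosome 7, around Kcnmb4, which encodes a potassium channel subunit, and Ifng, which encodes interferon gamma. Kcnmb4 (55751608 to 55806248, 11 probes) was at 0.49 on average (SD 0.78, n = 27; limma adjusted p = 0.0107) and was highly gained in 5 tumours: Chry EM 3, Amo BM 1, Amo SM 1, Amo SM 2 and Amo SM 4. Amo BM 1 and Amo SM 2 shared the start of this gain at 54855588 and 37 breakpoints in all, and they are counted here as 2 tumours. Without both of them the mean of Kcnmb4 was 0.32. Kcnmb4 did not pass within either set-up (0.55 in the first, 0.45 in the second), and with normexp it was at 0.31 and passed. Ifng, by 1 probe at 57621832 to 57621891, had the highest mean of all genes past the threshold under the naming rule, 0.89 (SD 0.93, limma adjusted p = 0.000401). That probe was above 0 in 25 of 27 tumours, but segments over it were called gained in only 8, with a high gain in 5. With adjoining segments joined, the high gains of the 5 tumours shared 2.37 Mb, from 55793495 to 58165300, with Kcnmb4, Cnot2, Rab3ip, Cct2, Lyz2, Nup107, Rap1b, Mdm1 and Ifng as its named genes. Cdk4, the cyclin-dependent kinase that p16 inhibits, was higher at 0.46 (SD 0.83; 0.0223) and highly gained in 2 tumours, and Myc, a transcription factor of cell growth, at 0.39 (SD 0.73; 0.0285) and highly gained in 2. With normexp, Ifng (0.23), Cdk4 (0.24) and Myc (0.12) kept their direction but did not pass. Cops5 on chromosome 5 was highly gained in 3 tumours, with a mean of 0.13 (SD 0.56) that did not pass (adjusted p = 0.348) and was 0.08 without Cro SM 2.

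**Figure D3:**
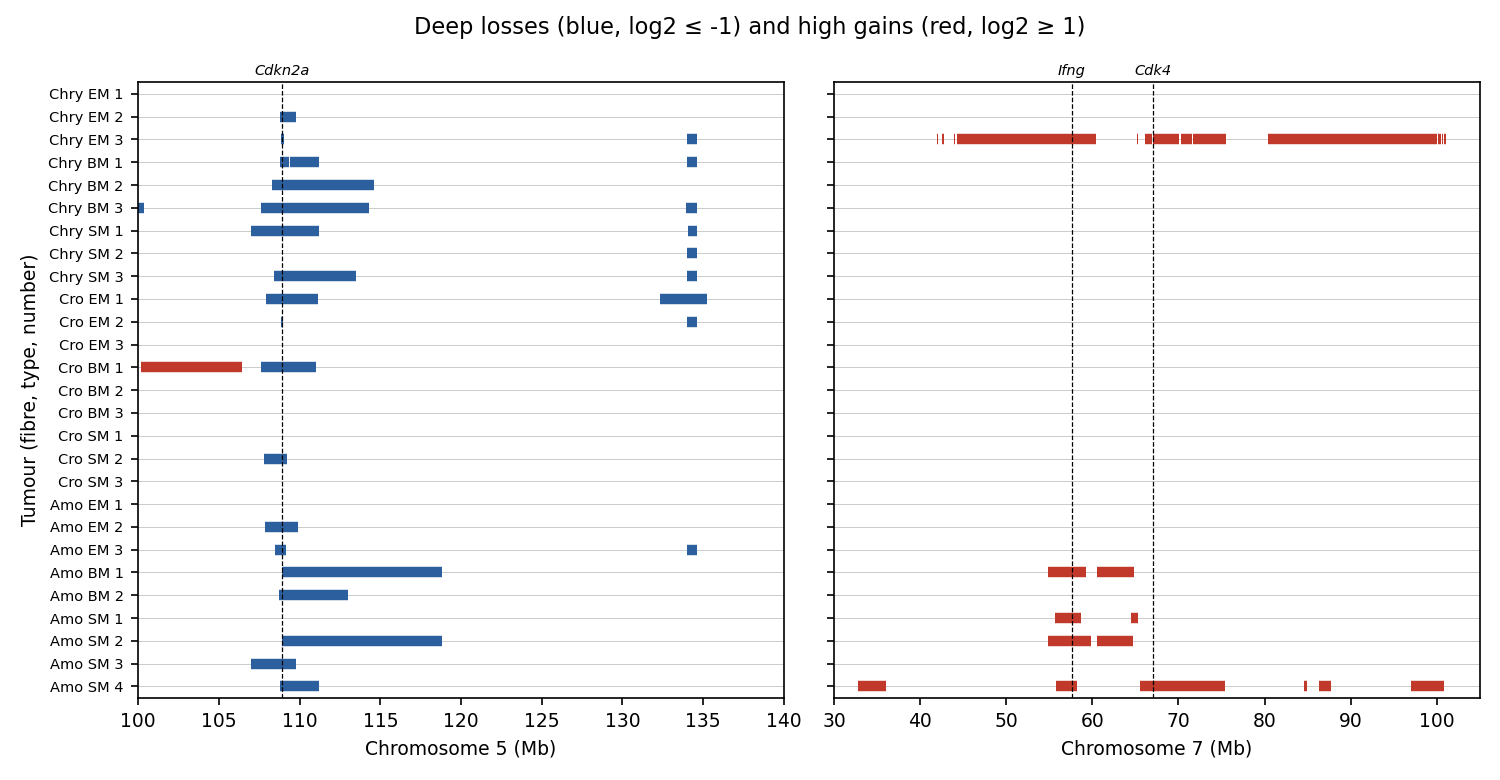
Deep losses (blue, mean log2 ratio at or below -1) and high gains (red, at or above 1) in parts of chromosomes 5 and 7, positions in Mb, with 1 line for each of 27 tumours and dashed lines at Cdkn2a, Ifng and Cdk4. Deep losses over Cdkn2a are seen in 18 tumours and high gains around Ifng in 5.

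Mdm2, which encodes a ubiquitin ligase, has no probe under its own name and lies in the same gain. The probes between its neighbours Lyz2 and Nup107, on chromosome 7 from 56612096 to 57100711, averaged 0.60 (SD 1.01, n = 27), with a gain called in 8 tumours, a high gain in 5, and the highest value, 3.66, in Amo SM 2. The same reading put Nf2 at -0.02 (SD 0.23), with a loss called in 5 tumours, and Bap1 at -0.02 (SD 0.29), with a loss in 3; both are tumour suppressors mutated in human mesothelioma. Tfrc, which encodes the transferrin receptor, was at 0.08 (SD 0.19), with a gain in 2 tumours. These interval values were added after seeing the files and were not tested.

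Among the tumour suppressors of mesothelioma, 0 of 3 measured genes passed limma over all genes, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. Rassf1, which encodes a Ras-binding scaffold protein, was at -0.07 (SE 0.06), with a loss called in 7 tumours and a gain in 0. Of 11 receptor tyrosine kinases and ligands, 2 were higher, also 2 when adjusted over the list alone: Erbb2 at 0.23 (SD 0.29, adjusted p = 0.00274), with a gain called in 4 tumours, and Met at 0.14 (SD 0.21, 0.0142). Of 10 oncogenes, 3 were higher, also 3 adjusted over the list alone: Myc, Ccnd1 (cyclin D1) at 0.21 (SD 0.40, 0.0338) and Mdm4, a relative of Mdm2, at 0.15 (SD 0.23, 0.0186). Gains were called in 1 tumour for Met and in 2 for Mdm4. Nras averaged 0.43 (SE 0.18) but did not pass (0.0804), and its mean was 0.27 without Cro EM 2 and 0.17 without Cro EM 2 and Cro SM 3. Centring on the mode ended the calls of Met, Myc, Ccnd1 and Mdm4, and normexp those of Myc, Ccnd1 (0.05) and Mdm4 (0.08), while Erbb2 was at 0.14 with normexp and passed.

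Of 8 cell cycle genes, 2 were higher and 1 lower, with the same counts adjusted over the list alone. Cdk4 and the kinase inhibitor gene Cdkn1b at 0.28 (SD 0.47, adjusted p = 0.0159) were higher, and Cdkn2c, which encodes the inhibitor p18 and lies on chromosome 5, was at -0.27 (SD 0.38, 0.00669), with a loss called in 12 tumours. Of 11 iron metabolism genes, 1 was higher and 1 lower, also when adjusted over the list alone: the iron exporter gene Slc40a1 at 0.19 (SD 0.27, 0.00963) and Ireb2, which encodes an iron regulatory protein, at -0.15 (SD 0.26, 0.0265). Of 11 genes of oxidative DNA damage repair, 0 were higher and 2 lower, against 1 higher and 2 lower adjusted over the list alone. The glycosylase gene Mutyh on chromosome 5 was at -0.30 (SD 0.43, 0.00665) and the endonuclease gene Apex1 at -0.25 (SD 0.40, 0.0141). Apex1, measured by 1 probe, was below 0 in 22 tumours, but segments there were called lost in 1 and gained in 2. Of 11 mesothelial and differentiation genes, 1 was higher and 2 lower, against 1 higher and 3 lower adjusted over the list alone. Vim (vimentin) was at 0.37 (SD 0.73, 0.0381), Pdpn (podoplanin) on chromosome 5 at -0.16 (SD 0.30, 0.0357) and Cdh2 (N-cadherin) at -0.14 (SD 0.18, 0.00800). The median of Vim was 0.09, and its mean was 0.27 without the dim array Amo EM 1, where it stood at 2.92. Gains were called in 3 tumours for Cdkn1b and in 2 each for Slc40a1 and Vim. With normexp Ireb2 (-0.07), Apex1 (-0.09), Pdpn (-0.06) and Cdh2 (-0.05) no longer passed, Cdkn2c (-0.13) and Mutyh (-0.14) still did, and Vim did not with centring on the mode. Within either set-up alone Myc, Ccnd1, Cdkn1b, Slc40a1, Mutyh, Vim, Pdpn and Cdh2 did not pass. Vim was at 0.76 in the first and 0.10 in the second set-up, and Cdkn1b at 0.53 and 0.11. Over all lists, 9 of 69 measured genes were higher and 10 lower, or 10 and 11 when adjusted over the lists alone.

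Over all 9270 autosomal genes, 2325 passed, 1226 above and 1099 below the reference (limma, n = 27). Centring on the mode changed this split to 605 above and 1467 below. Besides Cdkn2b and Elavl2, the lowest under the naming rule were Sln on chromosome 8 (-0.60, SD 0.75), Tas1r3 on chromosome 5 (-0.56, SD 0.46), Msl3l2 on chromosome 20 (-0.56, SD 0.62), BC108295 on chromosome 8 (-0.55, SD 0.48), Spout1 on chromosome 3 (-0.51, SD 0.27) and Svbp on chromosome 5 (-0.49, SD 0.69). Srpra and U57362 on chromosome 8 were both at -0.49. With normexp these 8 genes from Sln to U57362 still passed, at -0.31, -0.21, -0.15, -0.29, -0.19, -0.23, -0.25 and -0.15 in this order. Spout1 was below 0 in 27 of 27 tumours although only 1 had a loss called there. After Ifng, the highest were AB073717 on chromosome 7 (0.67, SD 0.91), AY724486 on chromosome 17 (0.55, SD 0.60), Kcns2 on chromosome 7 (0.51, SD 0.74) and C11h21orf140 on chromosome 11 (0.49, SD 0.50), of which AB073717 (0.40) and Kcns2 (0.24) did not pass with normexp and AY724486 (0.32) and C11h21orf140 (0.21) did. BC081786 (0.62), the transcription regulator genes Id1 (0.56), Cebpb (0.53) and Cebpe (0.50), and BC088247 (0.49) were as high, but with normexp they turned to -0.08, -0.11, -0.03, -0.09 and -0.02. The probes of Id1 and BC081786 were well above background on only 18 and 20 of 27 arrays, so their means and places in this order are uncertain. BC081786 (2.51), Id1 (2.60), Cebpb (2.78) and Cebpe (3.31) were highest on the dim array Amo EM 1. Without that array their means were 0.55, 0.48, 0.44 and 0.39. Gains were called in 1 tumour each for Id1, Cebpb and C11h21orf140 and in 2 each for BC081786 and Cebpe. Cebpb, Cebpe and Svbp did not pass within either set-up. All of these but Elavl2 were measured by 1 probe. The 11 arrays of the first set-up alone called 156 genes and the 16 of the second 1525.

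On average 10.9% of the probed autosomal genome was lost (SD 7.75, n = 27) and 5.00% gained (SD 5.06), together 15.9% (SD 9.1). Cro EM 1 had the most altered genome at 32.0%, and Cro BM 2 had no called change. Losses covered 11.9% in Chry (SD 5.34, n = 9), 14.6% in Cro (SD 9.12) and 6.11% in Amo tumours (SD 6.42). The difference of Cro from Amo did not pass after adjustment (exact permutation test, p = 0.0361, adjusted p = 0.165), nor did that of Chry from Amo (p = 0.0550, adjusted p = 0.165). The altered share was 16.6% in Chry, 18.5% in Cro and 12.6% in Amo, and 17.0% in EM, 13.9% in BM and 16.4% in SM tumours, with exact adjusted p from 0.790 to 0.903 over the 6 pairs. The dim arrays Amo EM 1 and Amo SM 1 were at 0.457% and 3.31%. No loss was called on either, which lowers the mean loss of Amo tumours. Normexp brought the mean altered share over all tumours to 5.2%.

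Chry and Cro tumours differed on chromosome 2, where 5 bins were lower in Chry: those starting at 149, 150, 151, 152 and 154 Mb. Over these bins Chry tumours averaged -0.26 (SD 0.28, n = 9), Cro tumours 0.36 (SD 0.40, n = 9) and Amo tumours 0.06 (SD 0.18, n = 9). They were below 0 in 7 of 9 Chry and above 0 in 8 of 9 Cro tumours. The difference was -0.62 (SE 0.13), and each bin had a limma adjusted p of 0.0470. Aadac, which encodes a deacetylase, and the receptor gene Gpr149 lie here, with differences of -0.74 (SE 0.14, adjusted p = 0.202) and -0.66 (SE 0.15, 0.563) that did not pass among genes. The call ended in most alternatives, among them normexp (difference -0.29, SE 0.08), the set-up as a block (-0.59, SE 0.13), scan day as a block (-0.48, SE 0.22) and without Cro EM 2 and Cro SM 3 (-0.48, SE 0.11). It was -0.37 (SE 0.19) within the first and -0.68 (SE 0.20) within the second set-up, neither with a bin past the threshold.

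No gene passed in Chry against Cro (0 of 9270 in limma, 348 at an unadjusted p under 0.05), and the remaining fibre pairs had no bin or gene past the threshold. Gata6, a transcription factor gene on chromosome 18, was at 0.15 in Chry and -0.22 in Cro tumours (difference 0.36, SE 0.08, adjusted p = 0.589). Chry against Amo gave 0 bins and 0 genes, with 119 and 379 at an unadjusted p under 0.05. Hmox1, which encodes the heme-degrading heme oxygenase 1, was at -0.29 (SD 0.35) in Chry and 0.16 (SD 0.20) in Amo tumours; Adamts5 was at -0.25 and 0.09, and the growth factor gene Fgf2 at -0.19 and 0.29 (all adjusted p = 0.943). Cro against Amo gave 0 bins and 0 genes, with 189 and 368 at an unadjusted p under 0.05. Ifng was at 0.42 (SD 0.42) in Cro and 1.69 (SD 1.15) in Amo tumours, a difference of -1.23 (SE 0.33, adjusted p = 0.949). AY387076 was at 0.06 and -0.24, and Ino80c at -0.29 and 0.07 (adjusted p = 0.949 for both).

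Tumour types did not differ at any bin or gene past the threshold in limma. SM against EM gave 0 bins and 0 genes, with 319 and 1197 at an unadjusted p under 0.05, SM against BM 0 and 0, with 177 and 678, and BM against EM 0 and 0, with 115 and 289. The protocadherin gene Pcdhb12 was at 0.27 (SD 0.29, n = 10) in SM and -0.44 (SD 0.51, n = 9) in EM tumours, M37227 at 0.20 and -0.56, and Tmem54 at -0.52 and 0.16 (limma adjusted p = 0.236 for each). Mri1 was at -0.30 in SM and 0.33 in BM tumours, the glucose transporter gene Slc2a8 at -0.40 and 0.17, and Agxt, which encodes a glyoxylate-detoxifying enzyme, at -0.15 and 0.40 (limma adjusted p = 0.674 for each). Fgfr3, which encodes a fibroblast growth factor receptor, was at 0.10 in BM and -0.43 in EM tumours, Elavl2 at -0.90 and -0.20 and Sh3glb1 at -0.12 and 0.30 (adjusted p = 1.00 for each, limma). With Cro EM 1 left out, SM against EM gave 16 bins and 6 genes, and with array weights SM against BM gave 83 genes, all lower in SM. The highest weights went to Cro BM 2 (3.90), which had no called change, the dim array Amo EM 1 (3.47) and Chry SM 2 (3.44). Those weights thus did not follow array quality.

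Fibre differences were not shown to depend on tumour type: 0 bins passed the interaction test in limma, with 38 at an unadjusted p under 0.05, against 30 bins past the threshold with scan day as a block. All 3 Chry BM arrays were of the first set-up, and all 3 Chry SM and 2 Amo BM arrays of the second. Within Chry, BM against SM thus cannot be separated from the set-up. Means of the 8 gene lists did not differ between fibres or tumour types in any of 48 exact permutation tests, of which 0 had an unadjusted p under 0.05. The smallest p was 0.0547, for the cell cycle genes, at -0.06 (SD 0.13) in Cro and 0.12 (SD 0.22) in Amo tumours (adjusted p = 0.676).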

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

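All tests of explanations in this part were chosen after the results they bear on had been seen. Chance flags about 1 in 20 groups by the rule for a tumour far from its group, and 9 of 77 groups and measures were picked out by it.

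Cro EM 2 and Cro SM 3 shared gains of chromosome 2, among them a high gain of 231 kb, from 198282992 to 198514228, with Nras and Ampd1. That gain stood at 4.61 in Cro EM 2 and 2.83 in Cro SM 3. All 6 gained segments of Cro EM 2 on chromosome 2 were present in Cro SM 3 at a share of 0.249 to 0.281 of their excess copy number, median 0.258. Identical DNA on both arrays is argued against, since 3 gains of Cro SM 3 on other chromosomes had a median share of 0.113 in Cro EM 2. DNA of Cro EM 2, or cells of its clone, in the Cro SM 3 sample stays open as a candidate explanation. The X excess had a share of 0.291. For the 12 steps of Cro EM 2 outside chromosome 2 the median share in Cro SM 3 was 0.326, but from -0.205 to 0.6. Of these, 2 steps at the window of chromosome 5 had the opposite direction, and 7 of the other 25 tumours had medians as near to that of chromosome 2. Measured by segments, as on chromosome 2, shares outside it were 0.53 to 0.94, except 0.11 over the window of chromosome 5. Segments can also hold changes that Cro SM 3 has of its own, so these shares do not decide either.

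Amo BM 1 and Amo SM 2 had bin profiles with a Pearson r of 0.817 across bins, which are not independent replicates, against at most 0.623 for pairs other than these and the Cro pair. They shared 37 breakpoints within 5 probes, among them the start of the loss over Cdkn2a at 108879683 on chromosome 5 and of the gain at 54855588 on chromosome 7; other pairs shared at most 13. DNA of Amo BM 1 in the Amo SM 2 sample is argued against by a gain of chromosome 9 whose share in Amo SM 2 was -0.0801, and DNA of Amo SM 2 in the Amo BM 1 sample by a loss of chromosome 7 with a share of -0.15. A common origin of both tumours, which the 37 shared breakpoints are consistent with, stays a hypothesis, because the labels do not say which tumours came from which animal.

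The window of chromosome 5 from 134044135 to 134592966 went both ways relative to the 2 Mb on each side. In 16 tumours the flanks were at -0.2 or lower; in 8 of these the window was at -0.5 or lower, and in 8 it lay above the flanks, in 4 of them (Cro SM 1, Cro SM 2, Amo BM 2 and Amo SM 2) by at least 0.15 and over 3 standard errors, as in Cro SM 2 with -0.72 in the flanks and 0.12 in the window. A candidate explanation is an inherited copy difference, with the window on only 1 of the 2 parental chromosomes, so that the outcome depends on which chromosome was lost; the count of 4 tumours is what it needs. The prediction also allowed no low window with flanks kept, and 3 tumours had one (Chry EM 3 at -2.52, Cro EM 2 at -1.41 and Amo EM 3 at -1.20), so it stays open. Separate focal deletions, independent of the flanks, stay open for the low windows. Fisher's exact test of low windows against lost flanks gave p = 0.427, which decides neither way. Such deletions could not leave the window above lost flanks. The excess was 0.50 in Cro SM 1, 0.85 in Cro SM 2, 0.52 in Amo BM 2 and 0.37 in Amo SM 2. These values argue against them for those 4 tumours. Deep segments ended at 134592966 in Chry EM 3, Chry BM 1, Chry SM 1, Chry SM 2, Chry SM 3 and Cro EM 2. In Chry BM 3 and Amo EM 3 they ended at 134606336, and in Cro EM 1 at 135266604. The cause of the shared ends was not tested.

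Several single tumours stood far from the rest of their group. Amo SM 4 had 17.1% of its genome gained, the highest among SM tumours, a mean of 0.559 over the oncogene list, the highest in Amo, and a mean of 0.188 over the mesothelial list, apart from the other Amo SM tumours. Cro SM 2 had the lowest Cdkn2a segment (-3.28) and the lowest mean of the 9p21 list (-2.66) in Cro. Cro BM 2, with no called change, stood apart from BM tumours at -0.0305 for the Cdkn2a segment and -0.0449 for the 9p21 list. Cro SM 1 had the lowest mean of the receptor tyrosine kinase list in Cro, -0.304, and the dim array Amo EM 1 the highest mean of the mesothelial list in EM, 0.364. On the X chromosome, outside the main tests, 12 of 27 tumours had a median log2 ratio of 0.6 or more. Rats of both sexes were used and sex is not labelled, so this cannot be read as gain of X in those tumours.

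Of 100 splits of the tumours, the real one included, 1 gave as many bins as Chry against Cro: the real split gave 5 and the highest other split 3. The real split is 1 of the 100, so this is the lowest value possible, and Chry against Cro was 1 of 6 pairs examined. A chance split is therefore not excluded, and the similar pairs also leave open whether the tumours are independent. The count of bins was 0 with 1 tumour of each similar pair left out, and the call ended in most alternatives. For these bins of chromosome 2, the set-up and the similar tumours Cro EM 2 and Cro SM 3 were also tested as sources of the difference of -0.62 (SE 0.13): it was -0.59 (SE 0.13) with the set-up as a block and -0.48 (SE 0.11) without both tumours, so neither accounted for most of it, though each ended the call. Where the real count was 0, all 100 of 100 splits gave as many by construction, which says nothing about chance. For bins the highest other split gave 11 for Chry against Amo, 0 for Cro against Amo, 31 for SM against EM, 0 for SM against BM and 4 for BM against EM. For genes it gave 0 for Chry against Cro, 0 for Chry against Amo, 50 for Cro against Amo, 411 for SM against EM, 1 for SM against BM and 10 for BM against EM. A random split of the SM and EM tumours thus called up to 411 genes, against a real count of 0. Its overlap with the real labels was not measured, and the structure of the tumours behind it was not tested.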

How the results depend on the processing

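Chosen after seeing the data were the set-up block, each set-up alone, the tests without similar pairs or dim arrays, the equal-weight replicate block and the recurrence count at or above its threshold; other alternatives were planned. Unless a cause is given, the cause was not tested.

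Of the 942 bins for all tumours, normexp left 543, 5-Mb bins gave 219 because only 522 bins were tested, and the first set-up with its 11 arrays gave 121. The 2325 genes became 156 in the first and 1525 in the second set-up, and the 19 listed genes 2 in the first, with fewer tumours each. The replicate block gave 941 bins with centred terms. A replicate block with equal weight per replicate number, run first, gave 229 bins, 965 genes (818 above, 147 below) and 10 listed genes; it weights the single tumour numbered 4 as much as 8 or 9 others, and the centred form was chosen after this was seen. Whether replicate numbers pair tumours is not labelled: same-numbered tumours of different groups had a median correlation of deviations of 0.047, with 33 of 100 pairs over 0.1, other pairs -0.0123, with 44 of 223, and 8 of 27 tumours correlated best with their own number. The centred replicate block gave 6 bins in Chry against Cro and 0 in the other pairs.

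The 5 bins of Chry against Cro became 0 with normexp, mode centring, scan day or set-up block, array weights, no covariate, each set-up alone, 1 tumour of each similar pair out, Cro EM 2 and Cro SM 3 out, or the 2 dim arrays out, 3 with well-above-background probes and 1 with 5-Mb bins. Array weights gave 1 gene (Aadac) for Chry against Cro and 83 for SM against BM. The second set-up alone gave 1 bin for Chry against Amo and 1 for SM against EM, and scan day as a block 30 interaction bins. The interaction was not fitted within a set-up, where groups had no tumour.

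The altered share of 15.9% was 5.2% with normexp, 33.2% at a call threshold of 0.15 and 6.48% at 0.4. Limits for calls were not rescaled for normexp, whose offset draws log ratios towards 0, so fewer segments reach them. How much of each fall this accounts for was not tested. The 18 tumours with Cdkn2a deeply deleted became 3 with normexp, 5 at -1.5, and 7 of 11 and 11 of 16 in the first and second set-up. The 176 recurrent bins became 8 with normexp, 298 at a call threshold of 0.15 and 7 in the first set-up; counting bins at the threshold, the reading used first, gave 204. With probes well above background on all arrays Cdkn2a had no probe and no count. Pairs of groups differing in altered share, Cdkn2a deletion or list means stayed at 0 in every alternative run.

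Leaving out each tumour in turn gave 852 to 968 bins, 1979 to 2522 genes and 17 to 23 listed genes for all tumours, an altered share of 15.3% to 16.5%, 17 to 18 tumours with Cdkn2a deleted and 140 to 193 recurrent bins. Chry against Cro ranged from 0 to 8 bins. It was 8 without Chry BM 2, and 0 without any 1 of Chry EM 1, Chry BM 1, Chry BM 3, Chry SM 1, Chry SM 3, Cro EM 3, Cro BM 3, Cro SM 1, Cro SM 2, Cro SM 3, Amo EM 1, Amo EM 3, Amo BM 2, Amo SM 1, Amo SM 2, Amo SM 3 or Amo SM 4. SM against EM ranged from 0 to 16 bins and 0 to 6 genes and Chry against Cro from 0 to 1 genes, each highest without Cro EM 1, and the interaction from 0 to 1 bins, highest without Chry BM 1. Other pairs stayed at 0.

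Among alternatives of named genes, 2196 kept direction and side of the threshold, 110 lost the call, 6 gained it and 5 reversed, all with normexp: BC081786 (-0.0792), Id1 (-0.109), Cebpb (-0.0329), Cebpe (-0.0889) and BC088247 (-0.0166). The first set-up alone lost 30 calls, the equal-weight replicate block 18, the second set-up alone 14 and normexp 11. Those kept include runs with 1 tumour left out, and genes named as not passing, which kept their side by not passing again. Probe noise, which limits what could be called, was highest in Amo EM 1 (0.71), Amo EM 2 (0.61) and Amo SM 1 (0.56), of which Amo EM 2 was not dim.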

Other observations

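Several high gains were each seen in a pair of tumours and were singled out here after their values were seen. On chromosome 8, Chry BM 2 and Chry BM 3 gained the genes of the apoptosis inhibitors Birc2 and Birc3 and of the Hippo pathway coactivator Yap1, at 1.57 in Chry BM 2 (3847092 to 5624690) and 2.71 in Chry BM 3 (4484794 to 4896703). Over all tumours Yap1 was gained in 4 and lost in 6. On chromosome 6, Chry SM 3 had a gain of 3.26 from 22790668 to 25095201, with Spdya, Ppp1cb and Plb1, and Amo EM 2 one of 1.08 from 21793826 to 24577523 over the same genes. On chromosome 19, Chry BM 3 (1.30) and Cro BM 1 (1.17) gained a stretch from 24621626 with Junb, Prdx2 and Calr. The receptor gene Kit on chromosome 14 lay in high gains of Amo BM 1 (1.37) and Amo SM 2 (1.32), the pair of similar profile.

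Some deep losses lay outside both shared windows of chromosome 5. Nfia, which encodes a transcription factor, lay in deep losses of chromosome 5 in Amo BM 1 (-1.95) and Amo SM 2 (-2.10). Fli1 and Ets1 on chromosome 8 lay in a deep loss of Amo SM 2 (-1.15); the matching segment of Amo BM 1 stood at -0.97. In all, 38 deep losses were called in 19 tumours and 110 high gains in 14 tumours.

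Medians of the X chromosome ran from -0.14 in Chry SM 1 to 1.16 in Amo SM 2, with 12 tumours under 0.2, 12 at 0.6 or more and 3 between. A run of 12 X probes went the other way, from 0.33 in Chry SM 1 to -1.87 in Amo EM 1, with a slope of -1.17 on the X median. Rats of both sexes were used and the sex of each is not labelled, so these medians cannot be read as tumour gain or loss of X. The cause was not tested.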
